A study of Mikania micrantha with 15 samples.

How the data were processed

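RNA sequencing (RNA-seq) was carried out on 5 tissues of Mikania micrantha, a fast-growing climbing vine of the daisy family. The tissues were flower, leaf, root, shoot apex (the growing tip of the shoot) and stem. Each tissue had 3 libraries, 15 in all, and the labels number them as replicates 1 to 3. Per the labels' protocols, cuttings of wild-type vines were rooted in water until roots reached 4 to 5 cm. They were then kept in Hoagland solution, a mineral nutrient medium, for 60 days at 24 °C with 16 h of light and 8 h of dark. Total RNA was extracted with TRIzol and the libraries were built and sequenced by a service company. The labels do not say whether replicates came from separate plants. The p-values here thus rest on the spread between these libraries, which may be partly technical. In the main fit that spread was estimated over all 15 libraries together, not within the tissues of a pair.

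The authors deposited 1 table of raw read counts per gene, with 41487 gene IDs and a column for each of the 15 libraries. The values are whole numbers that were not normalized. Reads were aligned with HISAT2, per the submitters' processing notes. The HISAT2 version, the counting program, the genome build, the annotation and the handling of strand and of multiply mapped reads are not given in the sources used here. Counts of near-identical copies, overlapping genes and antisense genes are therefore uncertain. The gene IDs are locus tags. The table does not pair them with gene names or products, and no genome or annotation was used here. The 42 gene lists that were fixed before the data were examined, such as photosynthesis, floral MADS-box and lignin genes, could thus not be matched to any ID. Their tests were not run, and genes are described by ID and by expression pattern. No coordinates are given for the same reason.

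Library totals ranged from 3777165 to 12817396 counts. No library held a read for 6275 of the IDs. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the tissue groups, which left 27055 genes holding 99.9% of all counts. Libraries were scaled by the trimmed mean of M-values (TMM). A model with 1 term per tissue was fitted to all 15 libraries together, so that the tissues shared 1 estimate of the spread, and quasi-likelihood F tests were made with glmQLFit and glmQLFTest. Adjusted p-values are Benjamini-Hochberg values over the genes tested, within each contrast. Genes that differed among tissues were counted at an adjusted p under 0.05 in the overall F test. In each of the 10 pairs of tissues a gene was called at an adjusted p under 0.05 and a change of at least 2-fold. A gene was called tissue-preferred when it was called higher in that tissue against every one of the other 4. CPM below were computed with edgeR's cpm function and the TMM factors and are given as mean ± SD, except that detection limits used CPM of the plain library totals. Correlations between libraries used log2 CPM with a prior count of 2. The tau index of tissue restriction was computed per gene from log2(mean CPM + 1) and runs from 0, even expression, to 1, expression in 1 tissue.

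Where all 3 libraries of a tissue held 0 reads, a fold is given as a lower bound, the mean CPM of the higher tissue over a floor of 3 counts over the 3 libraries of that tissue, which is 0.084 CPM in flower, 0.1 in leaf, 0.179 in root, 0.0717 in shoot apex and 0.148 in stem. Where 1 to 3 reads were seen, the ratio is that of the summed reads over the summed scaled totals, with a 95% exact (Clopper-Pearson) interval. Bounds and intervals cover counting error only.

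The rule for printing gene IDs was set before the data were examined, with a limit of 2 IDs in each direction of a comparison if no names were at hand. For each tissue, the tissue-preferred gene with the highest mean CPM is given. So is the one with the largest smallest-of-4 fold among those with a mean of at least 10 CPM. For each pair, the rule takes the called genes with the largest fold in each direction and a mean of at least 10 CPM in the higher tissue. The first of these is printed. IDs named outside the rule are said to be so.

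The procedure was tested on simulated counts drawn for the comparison of root with stem, with the real library sizes and the fitted gene dispersions, in which 67 genes were changed 2-fold, 67 genes 4-fold and 66 genes 8-fold in stem. Over 26267 genes, 87.9% of 8-fold changes, 64.2% of 4-fold changes and 19.4% of 2-fold changes were called. Of the 114 calls, 0 were false. Every other gene was drawn at the same mean in all tissues, and each gene had the same dispersion in all tissues. The real tissues differed in most genes and in replicate spread, so the simulation does not give the share of false calls in the real comparisons. Of simulated genes raised 4-fold in stem, 75.8% were called stem-preferred, against 5.88% of those raised 2-fold, the fold limit of the call.

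Replicate pairs were compared by chi-square over genes with at least 20 reads in the pair. Every pair differed by more than sampling noise, with 2.09 to 73.8 per degree of freedom, so no library was found deposited more than once. This does not show that replicates came from separate plants or RNA samples. The alternatives were DESeq2 1.42.0, relative log expression (RLE) factors, plain library totals, other low-count filters, an adjusted p under 0.01, the replicate number as a block, fits to the 6 libraries of a pair, and each library left out in turn. A fit without 3 libraries that stood apart and a fit without 9 abundant IDs were added after seeing the data.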

Results

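The transcriptomes of flower, leaf, root, shoot apex and stem of Mikania micrantha were compared, with 3 libraries per tissue. The series asks which genes differ among the organs of this rapidly growing vine. Library totals were 9567064 to 11770796 counts in flower, 7952050 to 12001006 in leaf and 3777165 to 10015399 in root. They were 11023970 to 12817396 in shoot apex and 5445218 to 9721732 in stem. The shallowest library was root replicate 2 and the deepest was shoot apex replicate 2.

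Flower expressed the widest range of genes and root and stem the narrowest. At least 1 CPM in all 3 libraries was reached by 23898 genes in flower, 22475 in shoot apex, 21194 in leaf, 20246 in stem and 20134 in root. This order was kept when every library was thinned to the smallest total, with 23088 genes in flower and 19973 in root. The number of IDs with a read was 30907 ± 202 in flower (SD, n = 3), and each flower library lay above each of the 12 libraries of other tissues. At that limit of 1 CPM, 17116 IDs were detected in all 5 tissues and 3083 in a single tissue. In flower, 720 IDs reached 1 CPM in all 3 libraries and in no library of another tissue, against 384 in root, 112 in shoot apex, 73 in leaf and 23 in stem. The flower count leaves out IDs that reached this limit elsewhere only in leaf replicate 1. An example is E3N88_15267, with 1175 reads there and 0 and 3 in leaf replicates 2 and 3.

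Most genes differed among the organs. The overall edgeR quasi-likelihood test called 24248 of 27055 genes, 89.6%, at an adjusted p under 0.05. The median tau index of tissue restriction was 0.268 over 26948 genes with a mean of at least 1 CPM in some tissue. A tau of at least 0.8 was found for 2194 genes, 8.14%. Of these strongly restricted genes, 1079 peaked in flower, 750 in root, 167 in leaf, 147 in shoot apex and 51 in stem.

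Libraries grouped by organ. Each of the 15 libraries correlated best with another library of its own tissue. Pearson's r across genes was 0.922 to 0.991 within tissues and 0.603 to 0.862 between tissues. These correlations are across genes, which are not independent replicates. The first principal component held 41.2% of the variance and set root apart, with stem between root and the other organs. The second held 20.9% and set flower apart. Stem correlated with root at a mean r of 0.775, above the 0.622 of flower, the 0.634 of shoot apex and the 0.675 of leaf with root. Leaf and shoot apex had a mean r of 0.820, and leaf and stem 0.830. The biological coefficient of variation between replicates was 14.002% in shoot apex and 15.6% in flower, but 29.5% in stem, 36.2% in leaf and 36.2% in root. The spread was uneven within the latter organs. Root replicates 2 and 3 had an r of 0.970, against 0.925 and 0.941 with root replicate 1. Stem replicates 1 and 2 had an r of 0.978, against 0.951 and 0.955 with stem replicate 3. Leaf replicates 2 and 3 had an r of 0.974, against 0.922 and 0.960 with leaf replicate 1.

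**Figure D1:**
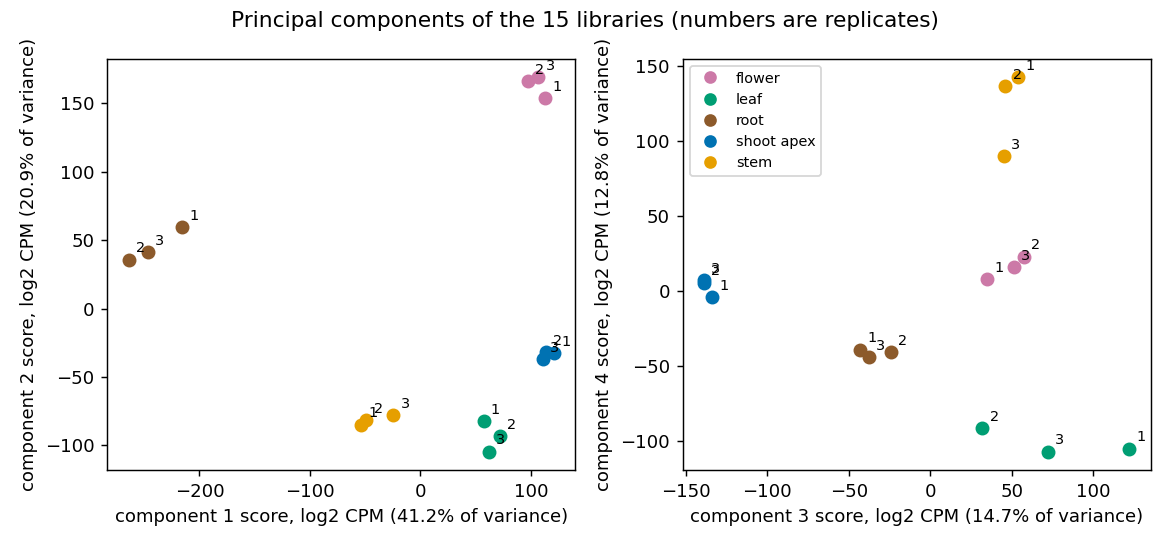
Scores of the 15 libraries on principal components 1 to 4 of log2 CPM, with each point 1 library, coloured by tissue and numbered by replicate. Component 1 (41.2% of variance) separates root from the other tissues, component 2 (20.9%) flower, component 3 shoot apex, and component 4 stem from leaf.

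The 10 pairs of tissues answered how many genes differed between any 2 organs. The main fit used a spread shared by all 15 libraries, although replicate spread differed between organs. With fits to the 6 libraries of a pair, calls fell in every pair except flower and shoot apex. They fell from 7730 to 5977 for root and stem, 11704 to 9911 for leaf and root and 9612 to 8090 for leaf and stem. They rose from 8413 to 8723 for flower and shoot apex. The counts of the main fit also depend on depth and replicate spread, which were unequal, and did not follow the correlations. Root and stem had a mean r of 0.775, and shoot apex and stem, with 12459 calls, one of 0.805. Root and shoot apex differed in the most genes, 14528, and root and stem in the fewest, 7730, by the edgeR quasi-likelihood test at an adjusted p under 0.05 and at least 2-fold. Root and shoot apex stayed the pair with the most calls without any 1 library, but flower and shoot apex became the pair with the fewest without flower replicate 2 (6976 against 7792 for root and stem), flower replicate 3 (7151 against 7760), or shoot apex replicate 1 (7683 against 7877), 2 (7509 against 7808) or 3 (7515 against 7790).

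**Figure D2:**
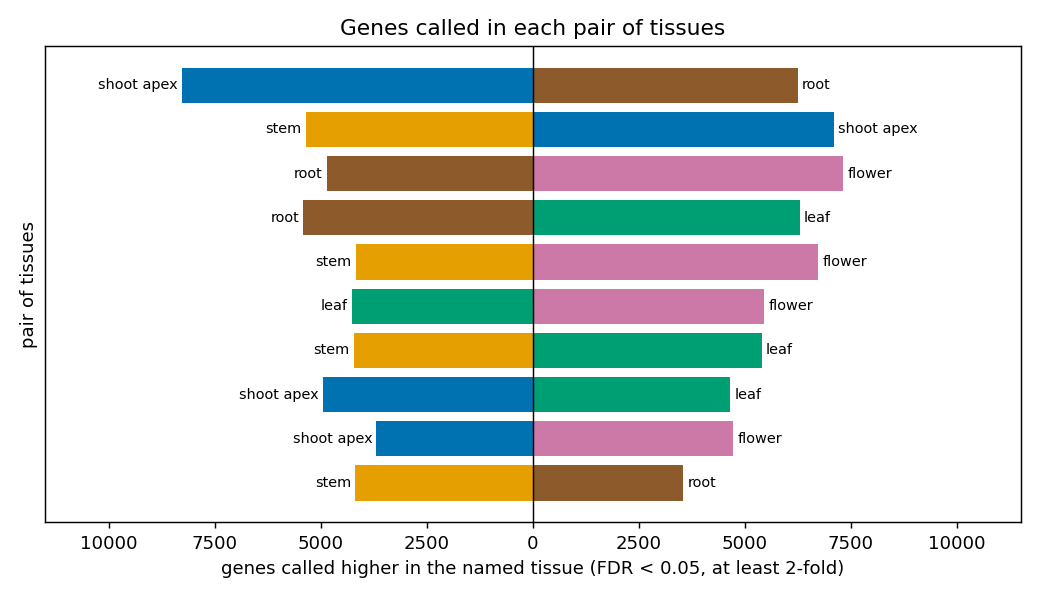
Number of genes called in each of the 10 pairs of tissues, with the bar to each side of 0 giving the genes higher in the tissue named at its end (edgeR quasi-likelihood test, adjusted p under 0.05, at least 2-fold, n = 3 libraries per tissue). Pairs are ordered from root and stem, 7730 genes, at the bottom to root and shoot apex, 14528 genes, at the top.

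Between root and shoot apex, 8276 genes were higher in shoot apex and 6252 in root. The gene E3N88_02871 was at 2078 ± 1144 CPM in root (SD, n = 3) and had no read in shoot apex, which puts it at least 28979-fold higher in root (edgeR adjusted p = 1.07e-08). In the other direction, E3N88_11962 was at 193 ± 16.0 CPM in shoot apex and had no read in root, at least 1078-fold higher in shoot apex (edgeR adjusted p = 2.21e-10). Of the calls in this pair, 43.0% were higher in root with TMM scaling and 30.4% with plain library totals.

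Between root and stem, 3551 genes were higher in root and 4179 in stem. The size of this excess in stem depended on the scaling. Root held 45.9% of the calls with TMM, 49.4% with RLE factors, 49.3% with DESeq2 and 42.5% with plain library totals. E3N88_06566 was at 730 ± 191 CPM in root and had no read in stem, at least 4917-fold higher (edgeR adjusted p = 7.79e-09). E3N88_11962, the gene also found in shoot apex and not in root, was at 304 ± 32.1 CPM in stem, at least 1700-fold above root (edgeR adjusted p = 2.66e-10).

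Between shoot apex and stem, 7107 genes were higher in shoot apex and 5352 in stem, which made it the pair with the second most calls, 12459, in the main fit. That rank was not stable. Flower and root had more calls with plain library totals (13127 against 12781) and without stem replicate 1 (12525 against 11683), but fewer with DESeq2 (12047 against 12605). E3N88_33417 was at 44.7 ± 4.22 CPM in shoot apex and at least 301-fold higher there than in stem, where it had no read (edgeR adjusted p = 6.01e-07). E3N88_38545 was at 196 ± 100 CPM in stem and at least 2736-fold higher than in shoot apex, where it had no read (edgeR adjusted p = 4.75e-06). The share of calls higher in shoot apex was 57.0% with TMM scaling and 70.8% with plain library totals.

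Leaf and root differed in 11704 genes, 6297 of them higher in leaf and 5407 in root. E3N88_08202 was at 231 ± 124 CPM in leaf and had no read in root, at least 1293-fold higher (edgeR adjusted p = 0.000908). In stem it was at 0.222 CPM in replicate 1, 0 in replicate 2 and 115 in replicate 3, and the cause of that difference was not tested. E3N88_06562 was at 611 ± 196 CPM in root and at least 6108-fold above leaf (edgeR adjusted p = 7.04e-07).

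Leaf and stem differed in 9612 genes, 5394 higher in leaf and 4218 in stem. E3N88_40560 was at 93.8 ± 30.0 CPM in leaf and at least 632-fold above stem (edgeR adjusted p = 9.09e-08). E3N88_36107 was at 254 ± 152 CPM in stem and at least 2539-fold above leaf (edgeR adjusted p = 5.46e-07).

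Leaf and shoot apex differed in 9605 genes, with 4657 higher in leaf and 4948 in shoot apex. E3N88_39524 was at 69.7 ± 1.92 CPM in leaf and at least 971-fold above shoot apex (edgeR adjusted p = 9.28e-08). E3N88_05243 was at 31.5 ± 4.67 CPM in shoot apex and at least 315-fold above leaf (edgeR adjusted p = 8.75e-08). Which of these organs held more of the calls depended on the scaling. Leaf held 48.5% of them with TMM, 52.4% with RLE factors and 36.9% with plain library totals.

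Flower differed from root in 12166 genes, from stem in 10895, from leaf in 9709 and from shoot apex in 8413. In each of the 4 pairs more genes were higher in flower, with 7318 against 4848 for root, 6733 against 4162 for stem, 5455 against 4254 for leaf and 4728 against 3685 for shoot apex. The share of calls higher in flower was 60.2% against root and 61.8% against stem with TMM scaling, and 73.3% and 75.0% with plain library totals.

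The flower transcripts with the largest folds had no read in the organ compared, and their levels in the other organs varied. E3N88_00553 was at 477 ± 34.7 CPM in flower and at least 2663-fold above root (edgeR adjusted p = 1.68e-10). It was also at 105 ± 13.2 CPM in stem, 81.4 ± 20.5 in leaf and 33.8 ± 2.16 in shoot apex. E3N88_15268 was at 598 ± 193 CPM and at least 8338-fold above shoot apex (edgeR adjusted p = 0.000638), and was at 43.2 CPM in leaf replicate 1, 0 in replicate 2 and 0.204 in replicate 3. E3N88_32204 was at 30.5 ± 4.72 CPM and at least 304-fold above leaf (edgeR adjusted p = 1.45e-05). E3N88_06562 of root was at least 7271-fold above flower, and E3N88_38442, at 128 ± 69.9 CPM in stem, at least 1525-fold above flower. E3N88_40875 of leaf was at least 197-fold above flower. E3N88_20997 was at 48.2 ± 8.12 CPM in shoot apex and had 1 read in the 3 flower libraries, a ratio of 1712 with a 95% exact interval of 307 to 67656.

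Tissue-preferred genes, which were called higher in 1 organ than in each of the other 4, numbered 1890 in root, 1694 in flower, 1413 in shoot apex, 1300 in leaf and 628 in stem. Their median expression in their own organ was 11.8 CPM in flower, 28.1 in shoot apex, 40.2 in root, 44.5 in stem and 52.8 in leaf. At least 100 CPM was reached by 481 of the root set, 404 of the leaf set, 191 of the stem set, 143 of the flower set and 112 of the shoot apex set.

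Flower-preferred genes took 6.66 ± 0.344% of the counts in flower (SD, n = 3) and 0.265 to 0.689% in the other libraries. The most abundant was E3N88_15267, at 1979 ± 724 CPM in flower. It had no read in stem, 1 in root and 6 in shoot apex, and was at least 13333-fold above stem (edgeR adjusted p = 0.000552). In leaf it was at 161 CPM in replicate 1, 0 in replicate 2 and 0.306 in replicate 3, and flower exceeded leaf by a log2 fold change of 5.22 ± 1.30 (SE, edgeR adjusted p = 0.0139). Without leaf replicate 1 that log2 fold change was 13.72, a fitted value that rests on few leaf reads. With DESeq2 the log2 fold change was 5.17 and the call was lost (adjusted p = 0.0914). The adjusted p of the alternatives ranged from 1.78e-07 to 0.0914. E3N88_15220, at 12.3 ± 1.95 CPM in flower, had no read in any other organ and was at least 68-fold above root, the smallest of its bounds.

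Leaf replicate 1 held low levels of flower transcripts. Without use of the leaf libraries, 114 genes were picked that had a mean of at least 50 CPM in flower and under 1 CPM in root, shoot apex and stem. All 114 had reads in leaf replicate 1, at a median of 4.03% of the flower level. In leaf replicates 2 and 3, 38 and 39 of them had a read and the median was 0. The median log2 ratio of flower to leaf mean CPM was 6.08 with all leaf libraries. Without leaf replicate 1 it was at least 9.27, with the leaf level set to the floor of 3 counts for the 81 genes under it.

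**Figure D3:**
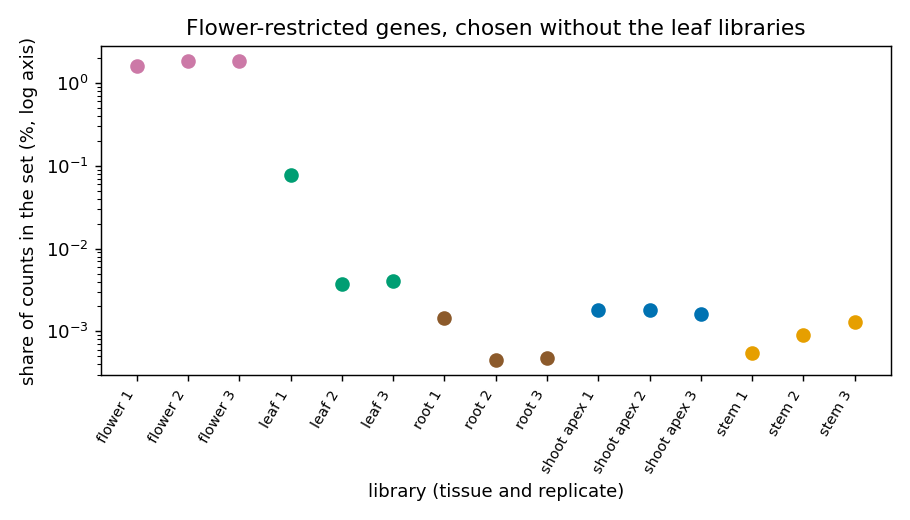
Share of each library's counts taken by 114 genes that were abundant in flower and under 1 CPM in root, shoot apex and stem, on a log axis, with each point 1 library coloured by tissue. Leaf replicate 1 is at 0.0784%, above leaf replicates 2 and 3 at 0.00378% and 0.00411% and below the flower libraries at 1.60 to 1.86%.

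Root-preferred genes took 16.0 ± 0.259% of the counts in root and 1.76 to 3.13% elsewhere. The most abundant was E3N88_01270, at 8593 ± 4479 CPM in root and 3279 ± 1784 CPM in stem, a log2 fold change of 1.39 ± 0.45 (SE, edgeR adjusted p = 0.0276). That call was lost without root replicate 1, with a log2 fold change of 0.88 and an edgeR adjusted p of 0.149, and without stem replicate 3, with 0.93 and 0.0979. Over all its alternatives the adjusted p ranged from 0.00549 to 0.149. E3N88_06562 was restricted further, at 611 ± 196 CPM in root with no read in any of the 12 other libraries. It was at least 4116-fold above stem (edgeR adjusted p = 1.8e-06).

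Leaf-preferred genes took 16.9 ± 3.98% of the counts in leaf and 1.70 to 5.04% elsewhere. The most abundant, E3N88_19494, was at 2870 ± 1993 CPM in leaf and 1362 ± 189 CPM in stem. Its log2 fold change over stem was 1.08 ± 0.42 (SE, edgeR adjusted p = 0.0471). Without leaf replicate 1 it was 0.41, with an edgeR adjusted p of 0.371. The call was also lost without leaf replicate 3 (1.15, edgeR adjusted p = 0.0673), stem replicate 1 (1.11, 0.0926), stem replicate 2 (1.15, 0.0814) or stem replicate 3 (0.96, 0.12), where the fold itself moved little. Over all its alternatives the adjusted p ranged from 0.00273 to 0.371. E3N88_16678 was at 19.0 ± 8.42 CPM in leaf, with no read in root or stem, 1 in flower and 2 in shoot apex. The leaf to shoot apex ratio was 364 with a 95% exact interval of 100.2 to 3013.

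Shoot apex-preferred genes took 6.71 ± 0.144% of the counts in shoot apex and 0.765 to 2.24% elsewhere. The most abundant was E3N88_17886, at 379 ± 64.9 CPM, against 118 ± 12.1 in flower, 110 ± 23.9 in root, 109 ± 36.4 in stem and 68.3 ± 53.5 in leaf. Its smallest log2 fold change was 1.68 ± 0.41 over flower (SE, edgeR adjusted p = 0.00506). E3N88_19812 was at 17.7 ± 1.01 CPM in shoot apex, with no read in root or stem, and was at least 98-fold above root. Its log2 fold change over flower was 7.18 ± 1.10 (SE, edgeR adjusted p = 7.72e-05). Without flower replicate 1 the fitted value was 10.33, which is not a measured fold, since flower replicates 2 and 3 held no read.

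Stem-preferred genes took 5.97 ± 0.724% of the counts in stem and 1.30 to 1.95% elsewhere. The most abundant was E3N88_14415, at 2046 ± 612 CPM in stem, against 509 ± 135 in root, 406 ± 44.6 in shoot apex, 299 ± 82.1 in leaf and 287 ± 47.8 in flower. Its smallest log2 fold change was 2.01 ± 0.27 over root (SE, edgeR adjusted p = 4.28e-05). E3N88_31316 was at 10.2 ± 1.62 CPM in stem, with no read in leaf or root. Its log2 fold change over flower was 6.34 ± 0.84 (SE, edgeR adjusted p = 3.14e-05).

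A few IDs took larger shares of the root and stem libraries with low totals. E3N88_24217 and E3N88_24214, chosen after their values were seen, were the most abundant IDs in root replicate 2, at 35389 and 31380 CPM. Together with 7 other IDs that varied with E3N88_24217 within tissues, they took 7.17% of the counts in root replicate 2, 5.01% in root replicate 3 and 0.695% in root replicate 1. In stem the 9 IDs took 5.05, 3.22 and 0.681% in replicates 1, 2 and 3, and in shoot apex 0.107 to 0.147%. Their shares in replicates 1, 2 and 3 were 1.07, 0.346 and 0.847% in leaf and 0.647, 1.19 and 1.43% in flower. Root replicate 1 and stem replicate 3 thus lay below leaf replicates 1 and 3 and flower replicates 2 and 3. E3N88_24217 was higher in root than in shoot apex by a log2 fold change of 5.73 (edgeR adjusted p = 8.69e-05). Root and stem did not differ in it by more than the spread between replicates (log2 fold change 0.55, edgeR adjusted p = 0.619).

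**Figure D4:**
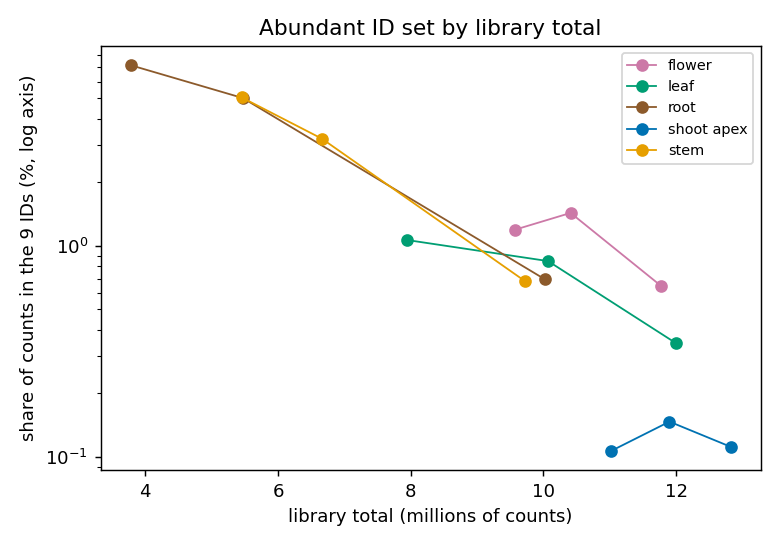
Share of counts taken by 9 co-varying abundant IDs, on a log axis, against the library total, with each point 1 library and lines joining libraries of a tissue in order of total. The share was 7.17% in root replicate 2, the library with the lowest total, and 0.107 to 0.147% in the shoot apex libraries.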

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

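The fit without 3 libraries and the fit without 9 abundant IDs were chosen after the data were seen. The 16 counts of genes (among all tissues, 10 pairs, 5 tissue-preferred sets) stayed within 1.5 times their value under each alternative run. DESeq2 moved them to between 86.1% (1458 flower-preferred genes) and 104.8%, and 93.9 to 97.8% of the calls of a pair were shared with it. Plain library totals gave 77.1% (484 stem-preferred genes) to 124% (1758 shoot apex-preferred genes), and moved the median log2 fold change of all genes by 0.39 between flower and root and by -0.44 between root and shoot apex, where RLE factors and DESeq2 moved it by 0.12 and 0.13. The FDR limit of 0.01 gave 71.1 to 89.5%, and fits to the 6 libraries of a pair 77.3% (5977 genes, root and stem) to 103.7%. RLE factors, no filter and a stricter filter stayed within 89.4 to 109.6%. Leaving out each library in turn gave 1052 to 1515 shoot apex-preferred genes, 523 to 813 stem-preferred, 1434 to 1977 flower-preferred, 1106 to 1529 leaf-preferred and 1850 to 2030 root-preferred genes. No pairing of the libraries by replicate number was seen. Of 30 same-numbered pairs, 3 correlated above 0.1 in their deviations from tissue means, and 2 of 15 libraries correlated best with their own number. With 3 libraries per tissue this cannot show that same-numbered libraries had no plant or batch in common. With the replicate block the counts were 93.3 to 98.7% of those without it, such as 7434 genes between root and stem. Of 289 refits of 29 named gene contrasts, 9 lost the call and 0 reversed, and DESeq2 gave no adjusted p for E3N88_15268 in flower over shoot apex. With the block, E3N88_19494 lost its call in leaf over stem (log2 fold change 1.02, adjusted p = 0.0742) and E3N88_15267 in flower over leaf moved to 8.91, and the other losses stand with the values of that gene, E3N88_01270 and E3N88_15267. Without leaf replicate 1, root replicate 1 and stem replicate 3 the stem-preferred count was 873. All 15 libraries stayed nearest to their own tissue with a prior count of 0.5. The gene list tests and their alternatives were not run for want of gene names. Depth limits root most, where 3 counts over its libraries equal 0.179 CPM.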

Other observations

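Of the tests in this part, only the regroupings of libraries for the counts among all tissues, in pairs and of tissue-preferred genes were planned; the gene sets below, their regroupings and the tests of the 3 patterns were chosen after the results were seen, except that the limits for the 246 flower genes were set before their values. Organs also shared sets of genes. In the same pairwise edgeR calls, 745 genes were higher in both flower and shoot apex than in each of the other 3 organs, 722 in both root and stem, and 369 in both leaf and shoot apex, while root and shoot apex shared 88. The largest set of 3 organs was that of flower, leaf and shoot apex, with 1049 genes above both root and stem. Root was the organ with the most genes below each of the other 4, 1828, against 815 in shoot apex, 645 in leaf, 380 in stem and 250 in flower.

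Whether arbitrary groups of libraries give as many genes was checked with 100 groupings of the 15 libraries, the real one included. The count of 24248 genes that differed among tissues stood against a highest other of 3686, and 1 of 100 groupings, the real one, reached it. The tissue-preferred counts stood against highest others of 0 for flower, 268 for leaf, 125 for root and 186 for shoot apex, with the real grouping the 1 that reached each count. For stem, with 628 genes, 2 of 100 reached the count, and the higher one, with 909 genes, kept the 3 root libraries together as its group. The other groupings with the most leaf-, root- and shoot apex-preferred genes likewise kept 3 libraries of an organ together. For the shared sets of 745, 722 and 1049 genes the highest other was 0. For genes below each other organ it was 0 in flower, 228 in leaf, 112 in root, 179 in shoot apex and 1030 in stem, where 2 of 100 reached the count of 380. The grouping with 1030 genes again kept the 3 root libraries together, which points to a structure of the samples. For these results the share of groupings that reached the count was under 0.05. The other groupings mix libraries of different organs, so low counts in them follow from the differences between organs. The share shows that the organ labels match the structure of the libraries, but it cannot exclude chance for a given set. The shared sets and the sets of genes below each other organ were also picked after the results were seen. For the 10 pairs, 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 7730 to 14528 genes and was the 1 of 10 with the most, and the highest other gave 47 for root and stem, 45 for leaf and root, 38 for leaf and stem, and 0 for the other 7 pairs.

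The first pattern is the presence of flower transcripts in leaf replicate 1. A candidate explanation is flower tissue or flower RNA in that sample, which was tested on 246 other genes, at 10 to 50 CPM in flower and under 1 CPM in root, shoot apex and stem. Of these, 88.2% had a read in leaf replicate 1, at a median of 2.70% of the flower level. In replicates 2 and 3, 35.0% and 30.9% had a read, with medians of 0. The medians met the limits set for them before this test, but the limit of 90% of genes with a read was not reached. At such a level the least abundant of these genes are expected to have few reads, so counting alone can leave some with none. The shortfall cannot decide the question, and this explanation stays undecided. Reads passed over from the 3 flower libraries would follow a mix of their profiles, but over the 63 genes with no read in leaf replicates 2 and 3 the best mix left a chi-square of 9.44 per degree of freedom, and the level ran from 1.27% to 11.0% of flower. Flower material of another stage than the deposited flower libraries, or expression of these genes in the leaf itself, stays open and was not tested.

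The second pattern is the share of the 9 abundant IDs around E3N88_24217, which was high where few reads were counted. A number of reads that stays constant or falls with the library is argued against, since these IDs had 69601 reads in root replicate 1, with 10015399 counts, and 270714 in root replicate 2, with 3777165. With deviations from tissue means over 15 libraries, the log2 reads of the set and the log2 total of all other IDs had a Pearson r of -0.87 (exact permutation within tissues, p = 0.008) and a Spearman rho of -0.79 (p = 0.018), both two-sided. With root replicates 1 and 2, the libraries farthest from the median, left out after the deviations were taken, r was -0.85. Root replicate 3 kept a deviation from a mean that holds them, so that value is not free of these libraries. These p-values only describe a relation noticed in the same libraries, also tried with the share of counts, whose denominator holds that total. RNA or library quality was not measured here and stays open. A difference between organs cannot give the relation within tissues, since deviations from tissue means were used, and within root alone the share ran from 0.695 to 7.17%. For the higher shares in root and stem than in shoot apex, a difference between organs stays open, since root and stem have low totals. Without sequences the kind of transcript is unknown.

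The third pattern is that genes with neighbouring ID numbers had similar profiles more often than genes with shuffled IDs. Most neighbours were not alike, with a median r of 0.107 for consecutive IDs, against a highest median of 0.021 in shuffles. Among pairs of consecutive IDs with a mean of at least 1 CPM, 3.52% had an r over 0.9 across the 15 libraries, against a highest of 0.741% in 200 shuffles of the IDs. Gene models split over consecutive IDs are argued against as the whole cause, since pairs 5 numbers apart were still at 1.14%. Consecutive IDs were both root-preferred in 244 pairs, against a mean of 94.2 in shuffles, and the longest run of root-preferred IDs held 8. The excess was seen in the other organs too. There were 170 such pairs against 75.95 in flower, 103 against 45.6 in leaf, 92 against 54.2 in shoot apex and 34 against 11.0 in stem. Tandem gene copies, reads shared between them, and regional control of expression may each contribute and stay open, because neither sequences nor positions were used here and ID order is not known to follow the genome.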
